A study of Mus musculus with 8 samples.

How the data were processed

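Polyadenylated RNA of mouse 2-cell embryos cultured with DMSO (4 libraries) or with 6 µM triclocarban (4 libraries) was sequenced as paired reads of 150 bases, per the labels' protocols. These protocols describe both a library preparation from total RNA at the microgram scale and 16 to 18 cycles of cDNA preamplification followed by another library kit, and do not say which was used for these embryos. The FPKM values were made by the authors and deposited as 1 table of 37310 genes with a column for each library. STAR, StringTie, featureCounts and DESeq2 1.30.1 and the genome build mm10 are named in the submitters' processing notes, with no role or order. Which tool made the FPKM, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. FPKM is relative to each library's own total, so a change of many abundant transcripts shifts the values of the others, and reads shared between close copies or overlapping antisense genes cannot be assigned from these values. The protocols name no molecular identifiers, so fragments need not be independent molecules and depth alone may understate the error.

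Each column was assigned to its library by its name, which is the sample description. No pair of libraries held identical values. Sums of FPKM ran from 477882 to 605986. Counts could not be recovered: with the exon length of the reference annotation, 8.1 to 10.0% of low values were within 0.02 of a whole number of fragments, where chance gives 4%. The worth of 1 fragment was itself chosen from these low values, which raises that percentage. The excess over 4% is therefore no evidence for the estimate. The depth was only estimated, as 6900000 to 14800000 fragments. The most common product of FPKM and exon length within a fixed window, shared by 54 to 94 genes per library, was taken as 1 fragment. The window bounds the depths that this estimate can give. No count test was run. Gene identifiers were matched to GENCODE M21 (GRCm38, the same assembly as mm10) for symbols and 1-based coordinates: 32620 identifiers (87.4%) and 12295 of those tested (95.0%) matched, 33.5% with the same version, so the table rests on another annotation release. In all, 9264 genes were at 0 in every library.

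Genes with at least 1 FPKM in at least 4 of the 8 libraries were tested (12941). The test was limma 3.58.1 (lmFit, eBayes with a mean-variance trend) on log2(FPKM + 1), with the treatment as the only term and 6 residual degrees of freedom, in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Changes are on the log2(FPKM + 1) scale, which understates those of low genes. A total of 33 gene lists were written before the data were examined, as were the test, the filter, the naming rule and most alternatives. Lists with at least 5 tested members were compared with the other genes by camera (preset correlation 0.01), and with an estimated correlation and by fry as alternatives. The balance of oocyte-derived and 2-cell-activated genes was the difference of their mean log2(FPKM + 1) per library, tested by an exact two-sided permutation test over 70 assignments. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

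The text names the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with no overlap between the groups' libraries and a mean of at least 5 FPKM in the higher group, leaving out predicted genes, pseudogenes and symbols without a name; up to 3 members of each list with the smallest adjusted p, where a list had any past the threshold, and otherwise the member with the smallest p as a value; and Duxf3, Zscan4d, Zfp352, Btg4, Cnot6l, Dnmt1, Dnmt3b, Tet3, Kdm5b, Sod1, Cyp1a1, Trp53 and Pou5f1, of which Cyp1a1 was below the filter. A few genes that the rule takes, or that a count refers to, are not reported here by name.

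The limma step was tested on data simulated from the 12941 tested genes of the comparison of triclocarban with control: it recovered 11% of genes changed by 1 log2 unit and 79% of those changed by 2, with 4 false calls, and camera called 0 of 32 unchanged sets. Genes were simulated as independent, so the 0 calls by camera do not cover lists of correlated genes. Only 100 genes were changed at each size, against 42.1% of genes called in the real data. The adjustment was therefore stricter in the simulation, and its percentages do not give the recovery in the real comparison. Alternatives were other pseudocounts, no filter or a stricter filter, 4 other scalings, the replicate number as a block, library weights, eBayes without trend or robust, removal of the GC and length trend, a minimum change, and leaving out each library. Leaving out controls 1 and 2, or 3 and 4, together was added after the principal components were seen.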

Results

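Triclocarban, an antibacterial compound used in soaps and other personal care products, was added to the culture medium of fertilized mouse eggs, and polyadenylated RNA of the resulting 2-cell embryos was sequenced. The 2-cell stage is the time of the major activation of the embryo's own genome in the mouse, when transcripts stored in the oocyte are cleared and embryonic transcripts take their place. The data held 4 libraries of control embryos, cultured with the solvent DMSO, and 4 libraries of embryos cultured with 6 µM triclocarban. The labels also name 2 and 4 µM in the culture experiment, but all 4 treated libraries are labelled 6 µM. The comparison between the groups addressed whether exposure changes the passage from maternal to embryonic transcripts and the expression of epigenetic regulators, as the series title states. The labels do not say whether the 4 libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. Neither the hour of collection nor a sequencing batch is stated.

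Values were FPKM (fragments per kilobase of transcript, scaled to the library's mapped fragments) for 37310 genes. The depth was estimated from the most common product of FPKM and exon length within a fixed window, taken as the worth of 1 fragment. The window bounds the estimates, so they are rough. The estimated depth was 14800000, 12900000, 13100000 and 11300000 fragments in control libraries 1 to 4. In triclocarban libraries 1 to 4 it was 13600000, 6900000, 10900000 and 10600000. The number of genes with at least 1 FPKM was 13541, 13434, 13028 and 12828 in the control libraries and 11957, 11788, 11925 and 11855 in the treated ones. Mitochondrially encoded genes took 16.6, 17.6, 22.6 and 24.3% of the FPKM sum in the controls and 11.1, 17.6, 13.7 and 13.1% in the treated libraries. The correlation of log2(FPKM + 1) across genes was 0.909 to 0.982 between treated libraries, 0.874 to 0.976 between control libraries and 0.696 to 0.884 between the groups. The first principal component held 69.1% of the variance and separated the groups, with scores of 27.8, 36.5, 101.7 and 97.8 for control libraries 1 to 4 and -69.6, -65.0, -62.7 and -66.5 for the treated libraries. The controls lay in pairs, 1 with 2 and 3 with 4, along the component that parted the groups. Triclocarban library 2, which had the lowest estimated depth, stood apart on the second component at -63.3.

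**Figure D1:**
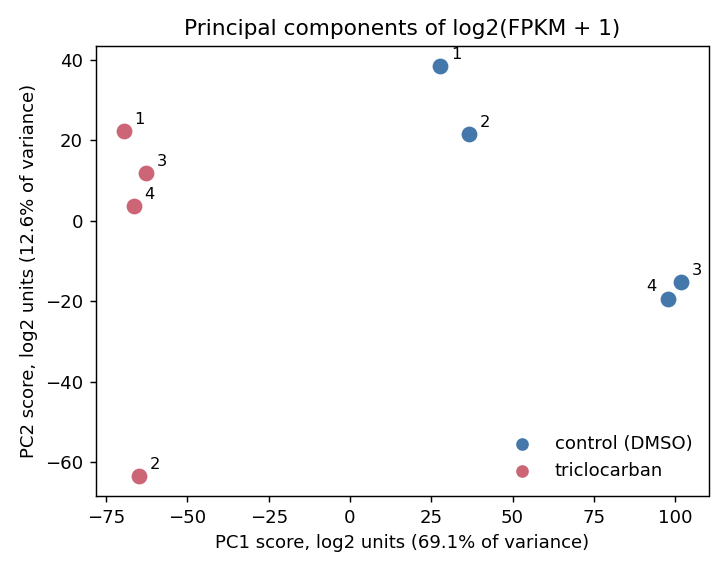
Scores of the 8 libraries on the first (horizontal) and second (vertical) principal components of log2(FPKM + 1), in log2 units, with the replicate number beside each point. The 4 triclocarban libraries lie between -69.6 and -62.7 on the first component and the controls between 27.8 and 101.7, with controls 1 and 2 nearer to the treated libraries than controls 3 and 4.

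With triclocarban, many oocyte-derived transcripts had a higher FPKM, and many transcripts for ribosomal proteins and ribosome assembly a lower one. These 3 lists passed camera with a fixed correlation between genes and did not with an estimated one (adjusted p = 0.85 for each). FPKM is a share of each library's polyadenylated RNA, so the amount of a transcript per embryo was not measured. Of 12941 genes tested, 1466 were higher and 3981 lower with triclocarban (limma, Benjamini-Hochberg adjusted p under 0.05), together 42.1% of the genes tested. An absolute change of at least 1 on the log2(FPKM + 1) scale was reached by 1079 of the higher and 3304 of the lower genes. All 4 treated libraries lay above all 4 controls for 1322 genes and below them for 3882, where chance gives 2.86% of genes in either direction together. The share of higher genes among those changed depended on the scaling. It was 26.9% with the FPKM as deposited. It was 45.3% (2638 higher, 3188 lower) after median-of-ratios scaling and 50.6% (2915 higher, 2847 lower) after quantile normalization. The median log2 change of all tested genes was -0.19 as deposited, 0.06 after median-of-ratios scaling and 0.14 after quantile normalization. It was -0.30 without controls 3 and 4 and -0.12 without controls 1 and 2, and list medians in those settings are given as they are. List medians over all 8 libraries are given as they are and relative to -0.19. The number of higher genes was 971 without control 3, 953 without control 4, 695 without both and 2838 without controls 1 and 2. The leaving out of pairs was chosen after seeing the principal components.

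The largest rise on the log2(FPKM + 1) scale was that of Rgs2, a regulator of G protein signalling (ENSMUSG00000026360.3, chromosome 1, 143999338 to 144004161, minus strand, GRCm38). Its FPKM was 31.3 ± 9.95 in controls and 413.6 ± 140.1 with triclocarban (SD, n = 4 each), a log2 change of 3.67 with a standard error of 0.32 (limma adjusted p = 4.39e-05). With a pseudocount of 0.1 it was 3.71, and the caspase gene Casp8 was at 3.73. Ooep, which encodes a member of the subcortical maternal complex of oocytes and early embryos (chromosome 9, 78376109 to 78378725, minus strand), went from 67.7 ± 40.1 to 445.9 ± 97.9 FPKM, a log2 change of 2.88. The oocyte-specific homeobox gene Obox7 and the prefoldin subunit gene Pfdn4 each rose by 2.89. Chac2, which encodes an enzyme that degrades glutathione, rose by 2.90. Ifitm6, a gene of the interferon-induced transmembrane family, rose by 2.91. Fam90a1a rose by 2.92 and the immunoglobulin light chain segment Iglc2 by 2.95. Obox7, Fam90a1a and Iglc2 have close copies in the genome, and how reads shared between copies were counted is not stated, so their values are uncertain. For all genes named in this paragraph, controls 1 and 2 lay above controls 3 and 4. Ooep, for example, was at 86.22, 115.42, 36.14 and 32.9 FPKM in controls 1 to 4. The size and order of these rises therefore depended on the pair of controls.

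The deepest fall on the log2(FPKM + 1) scale was that of Ctsc, which encodes the lysosomal protease cathepsin C (ENSMUSG00000030560.9, chromosome 7, 88278085 to 88310888, plus strand). It had 101.3 ± 44.2 FPKM in controls and 1.64 ± 0.79 with triclocarban (SD, n = 4 each), a log2 change of -5.21 with a standard error of 0.36 (limma adjusted p = 3.09e-05). The order depended on the pseudocount: with 0.1, Inka1 was at -6.79 and Ctsc at -5.86, and with 5, Cd63 was at -4.02, Spic at -3.95 and Ctsc at -3.91. Spic, a transcription factor of the ETS family, went from 197.6 ± 179.8 to 3.82 ± 2.95 FPKM, a change of -4.92. Its FPKM was 43.89, 40.97, 370.55 and 334.99 in controls 1 to 4, so the size of the fall depended on the pair of controls. Controls 1 and 2 also lay below controls 3 and 4 for Ctsc, Cd63, Stmn3, Exoc3l2, Nop16 and Folr1, but not for Inka1. Inka1, which encodes an inhibitor of a p21-activated kinase, changed by -4.59. Cd63, which encodes a tetraspanin of endosomes, changed by -4.57 and the stathmin family gene Stmn3 by -4.53. Exoc3l2, a relative of exocyst genes, changed by -4.45. Nop16, which encodes a nucleolar protein of ribosome assembly, went from 103 ± 66.7 to 3.95 ± 2.50 FPKM, a change of -4.29. The folate receptor gene Folr1 went from 122.2 ± 58.7 to 6.61 ± 4.80 FPKM, a change of -4.26.

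Among oocyte-derived transcripts, 38 of 76 tested members were higher, 2 were lower and 36 did not pass the threshold. Adjusted over the list alone, 41 were higher and 2 lower. The lower ones were Zp3, a gene of the egg coat, and the ion channel gene Trpm7, at -1.14 and -1.02. The median log2 change was 1.23, and 1.43 relative to all genes. Besides Rgs2 and Ooep, the uncharacterized gene E330021D16Rik went from 133.5 ± 18.0 to 800.7 ± 197.4 FPKM (SD, n = 4 each). The oocyte gene Nlrp4b, which has close relatives, went from 12.9 ± 3.28 to 64.6 ± 7.10 FPKM. Btg4, an adaptor of the deadenylase complex that clears maternal mRNA (chromosome 9, 51060901 to 51119875, plus strand), went from 1635 ± 910.8 to 4269 ± 1100 FPKM, a log2 change of 1.52 (limma adjusted p = 0.0109). Its adjusted p was 0.0589 with no filter on low genes and 0.0944 without controls 3 and 4. The list's shift had a camera adjusted p of 4.45e-15 with the preset correlation between genes, and adjusted p = 0.85 with an estimated correlation. The mean of its members, relative to all tested genes, was 3.70, 3.53, 2.62 and 2.64 log2 units in controls 1 to 4, so it differed between the pairs of controls. It was 4.96, 4.28, 4.80 and 4.79 in treated libraries 1 to 4. The list's median was 0.50 without controls 3 and 4 (28 higher) and 1.93 without controls 1 and 2 (57 higher).

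Genes known for their activation at the 2-cell stage went both ways: 8 of 48 tested members were higher, 19 lower and 21 did not pass the threshold. Adjusted over the list alone, 9 were higher and 20 lower. Eif1a, a translation initiation factor used as a marker of this activation (ENSMUSG00000057561.3, chromosome 18, 46597701 to 46616456, plus strand), went from 49.0 ± 20.2 to 5.19 ± 2.02 FPKM (SD, n = 4 each), a log2 change of -2.97 with a standard error of 0.35 (limma adjusted p = 0.000109). Snai1, a transcriptional repressor, went from 33.1 ± 6.65 to 6.15 ± 1.33 FPKM, and Btg1, an antiproliferative gene, from 14.4 ± 2.85 to 2.04 ± 0.75. Zfp352, a gene expressed at high levels at the 2-cell stage, went from 218.3 ± 24.2 to 106.4 ± 42.0 FPKM (log2 change -1.14, adjusted p = 0.0181), and its adjusted p was 0.0503 with median-of-ratios scaling. Duxf3, the gene of the transcription factor DUX, which acts early in genome activation (chromosome 10, 58229979 to 58232675, minus strand), had 0.32 ± 0.28 FPKM in controls and 1.41 ± 0.11 with triclocarban (log2 change 0.90, adjusted p = 0.00461). Zscan4d, a target of DUX (chromosome 7, 11161374 to 11166159, minus strand), had 88.1 ± 37.3 and 137.5 ± 57.7 FPKM, which did not pass the threshold (log2 change 0.60, adjusted p = 0.274). Without triclocarban library 2 it did (log2 change 0.98, adjusted p = 0.0347). Chosen after their values were seen, Zscan4c and Zscan4f were among the 8 higher members, and the homeobox gene Obox6 and the chromatin factor Dppa4 among the 19 lower ones. Genes of the Zscan4, Obox, Usp17l and Pramel families and Duxf3 have near-identical copies and are uncertain in the same way. The list as a whole was not shifted against the other genes (camera adjusted p = 0.716, median -0.44, and -0.24 relative to all genes). Without triclocarban library 2 its median was -0.16, where that of all tested genes was -0.22.

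The mean log2 expression of oocyte-derived minus 2-cell-activated genes (75 and 47 genes, with 1 gene of both lists left out) was 1.83, 1.63, 0.54 and 0.40 in controls 1 to 4 and 3.28, 3.05, 2.87 and 2.93 in the treated libraries. The group means were 1.10 ± 0.73 and 3.03 ± 0.18 (SD, n = 4 each), and the difference of 1.93 had an exact two-sided permutation p of 0.0286, the smallest that the 70 assignments of the libraries allow. The difference was 2.56 without controls 1 and 2 and 1.3 without controls 3 and 4, each with an exact p of 0.0667, the smallest possible with those libraries.

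**Figure D2:**
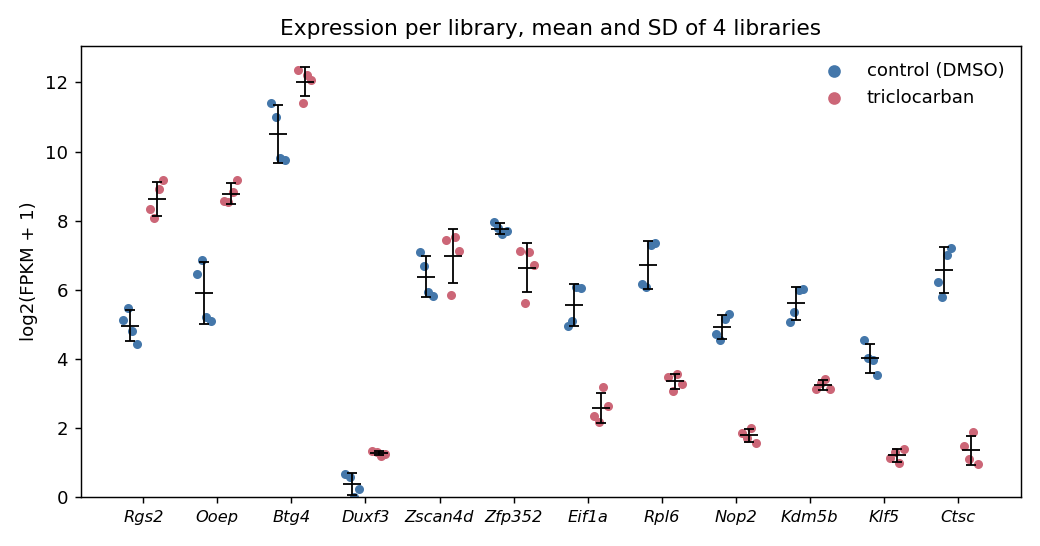
log2(FPKM + 1) of 12 named genes in each library (points), with the mean and SD of the 4 libraries per group (black lines). Rgs2, Ooep, Btg4 and Duxf3 lie higher with triclocarban, Zfp352, Eif1a, Rpl6, Nop2, Kdm5b, Klf5 and Ctsc lower, and the groups overlap for Zscan4d.

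Regulators of genome activation fell in 22 of 52 tested members and rose in 1, Obox5, which belongs to a family of close copies. The counts were the same when adjusted over the list alone. Klf5, a transcription factor of the early embryo (chromosome 14, 99298691 to 99315036, plus strand), went from 15.7 ± 4.88 to 1.32 ± 0.29 FPKM (SD, n = 4 each). The retinoic acid receptor gene Rarg changed by -2.13 and the ETS family gene Gabpa by -2.54 on the log2 scale. The list's median was -0.74, and -0.55 relative to all genes (camera adjusted p = 0.0515, which missed the threshold). Pluripotency and lineage genes had 14 of 28 members lower, among them Klf5, Tbx3 at -2.57 and Wwtr1, a cofactor of Hippo signalling, at -1.90. The 1 higher member was Gata3, a trophectoderm factor, at 2.74 (camera adjusted p = 0.216). With median-of-ratios scaling 2 were higher and 13 lower, and with quantile normalization 5 and 11. Pou5f1, the pluripotency factor OCT4, had 18.2 ± 10.7 FPKM in controls and 32.1 ± 4.65 with triclocarban (log2 change 0.96, limma adjusted p = 0.0647). It passed the threshold without control 1 (adjusted p = 0.0161) and without control 2 (adjusted p = 0.0379). It also passed with median-of-ratios scaling (adjusted p = 0.0122) and quantile normalization (adjusted p = 0.0215).

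Ribosomal protein genes were lower in 73 of 78 tested members and higher in 0. Adjusted over the list alone, 76 were lower and 1 higher. Rpl6 (ENSMUSG00000029614.9, chromosome 5, 121204481 to 121209241, plus strand) went from 114 ± 52.4 to 9.23 ± 1.51 FPKM (SD, n = 4 each), a log2 change of -3.38 with a standard error of 0.34 (limma adjusted p = 5.86e-05). Rpl13 changed by -2.94. The list's median was -2.19, and -2.0 relative to all genes, with a camera adjusted p of 1.56e-15, and adjusted p = 0.85 with an estimated correlation. Its mean relative to all tested genes was 2.33, 2.65, 3.79 and 3.76 in controls 1 to 4 and 1.34, 1.29, 1.41 and 1.46 in treated libraries 1 to 4. Without controls 3 and 4 the median was -1.46 (63 lower) and without controls 1 and 2 it was -2.77 (76 lower). Ribosomal protein genes have many processed pseudogenes, and 59 of 86 tested ones named after such genes were lower too.

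Of the genes for ribosome assembly, 61 of 81 tested members were lower and 2, the kinase gene Riok1 and Bms1, were higher. Adjusted over the list alone, 67 were lower and 3 higher. Nop2, which encodes a nucleolar rRNA methyltransferase (ENSMUSG00000038279.8, chromosome 6, 125131909 to 125144753, plus strand), went from 30.0 ± 7.55 to 2.47 ± 0.45 FPKM (SD, n = 4 each). Bop1 went from 16.2 ± 2.96 to 0.79 ± 0.17 FPKM and Rrp9 from 52.8 ± 11.7 to 5.3 ± 0.90. The list's median was -1.65, and -1.46 relative to all genes, with a camera adjusted p of 4.26e-10, and adjusted p = 0.85 with an estimated correlation. Its mean relative to all tested genes was 0.98, 1.15, 2.14 and 2.09 in controls 1 to 4 and 0.33 to 0.41 in the treated libraries. Without controls 3 and 4, 49 members were lower. Translation factors were lower in 25 of 49 members, including Eif2b5 at -2.12 and the poly(A)-binding protein gene Pabpc1 at -2.76 (camera adjusted p = 0.275). The 4 higher ones were Eif1b at 2.49, Eef1e1, Eef1b2 and the oocyte form Eif4e1b. With median-of-ratios scaling 8 were higher and 20 lower, and with quantile normalization 8 and 21. Aminoacyl-tRNA synthetase genes were higher in 4 of 21 (Tars, Lars, Wars and Nars) and lower in 7, such as Yars at -2.73, Mars at -1.55 and Aars at -1.50 (camera adjusted p = 0.803). This split turned to 8 higher and 5 lower with median-of-ratios scaling or quantile normalization.

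Histone methylation enzymes went both ways, with 9 of 56 members higher and 20 lower. Kdm5b, a demethylase of histone H3 lysine 4 (ENSMUSG00000042207.10, chromosome 1, 134560171 to 134635285, plus strand), went from 49.97 ± 16.1 to 8.48 ± 0.93 FPKM (SD, n = 4 each), a log2 change of -2.37 with a standard error of 0.28 (limma adjusted p = 0.000113). The H3 lysine 9 methyltransferase gene Suv39h1 changed by -2.94 and the arginine methyltransferase gene Prmt5 by -2.52. Of the histone acetylation genes, 10 of 38 were lower, including the deacetylase gene Hdac1 at -1.85, Mta2 at -2.93 and Ing1 at -1.77, and 2 were higher, Rbbp7 and Sin3b. DNA methylation genes were lower in 7 of 22, including Gadd45a at -1.95, Gadd45b at -2.34 and Uhrf2 at -1.35, and higher in 1, Dppa3, an oocyte factor. Dnmt1, the maintenance DNA methyltransferase, had 9.35 ± 1.87 and 13.9 ± 2.62 FPKM (adjusted p = 0.12). It passed the threshold with median-of-ratios scaling (adjusted p = 0.0205) and quantile normalization (adjusted p = 0.0109). Dnmt3b did not pass it, with 3.56 ± 1.16 and 2.61 ± 0.10 FPKM (adjusted p = 0.355). The DNA demethylation enzyme gene Tet3 did not either, with 37.2 ± 18.0 and 58.7 ± 30.6 FPKM (adjusted p = 0.217). Genes of the RNA methylation mark m6A were higher in 3 of 21 (Mettl3, Ythdc2 and Virma) and lower in 6, such as Cbll1 at -1.97, Igf2bp1 at -1.81 and Ythdf2 at -1.62. Imprinted genes were lower in 6 of 19, including Mcts2 at -2.07, Jade1 at -1.67 and Phlda2 at -1.70, and higher in 1, Airn. Mcts2 is a retrogene of Mcts1, with which it could share reads. The excess of lower members narrowed with the scaling: histone methylation genes were 12 higher and 16 lower with median-of-ratios scaling and 11 and 13 with quantile normalization. Histone acetylation genes were 5 and 8, and 5 and 6. DNA methylation genes were 3 and 4, and 2 and 3, and were even, with 5 each way, without controls 1 and 2. None of these 5 lists was shifted against the other genes (camera adjusted p of 0.803, 0.907, 0.964, 0.803 and 0.801).

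Genes of maternal mRNA decay had 8 of 45 members higher and 13 lower. The split turned to 16 higher and 8 lower with median-of-ratios scaling and to 13 and 9 with quantile normalization, and it was 17 and 13 without controls 1 and 2. Cnot10, a subunit of the CCR4-NOT deadenylase, changed by -2.21, Pabpc1 by -2.76 and Tob1 by -2.07. Cnot6l, a catalytic subunit, had 92.5 ± 75.9 and 113.1 ± 60.8 FPKM (SD, n = 4 each; limma adjusted p = 0.487). Splicing genes were higher in 15 of 80 and lower in 27, such as Snrpb at -3.14, Snrpc at -2.12 and Sf3b5 at -2.27. They were 17 higher and 21 lower with median-of-ratios scaling and 16 and 22 with quantile normalization. Proteasome and ubiquitin genes were higher in 10 of 43, such as Psmd10 at 1.98, and lower in 16, such as Psmb5 at -3.58 and Psme1 at -1.85. With either of those scalings, 14 were higher and 12 lower, and without controls 3 and 4 the numbers were equal at 11. Cell cycle genes were higher in 10 of 59, such as the securin gene Pttg1 at 2.07, and lower in 19, such as the condensin gene Ncapd2 at -1.97 and the kinase gene Wee1 at -1.96. With quantile normalization 14 were higher and 15 lower, and 18 were higher and 14 lower with median-of-ratios scaling. DNA replication genes were higher in 8 of 61, such as Rfc3 at 1.94, and lower in 17, such as the cyclin gene Ccne1 at -2.70 and Rpa2 at -2.83. They were 11 higher and 14 lower with median-of-ratios scaling and 10 and 12 with quantile normalization. Histone genes were higher in 5 of 24 (Hist3h2ba, H1foo, Hist2h2aa1, Hist1h1a and Hist1h1e). They were lower in 5 (H2afj at -2.15, H2afv at -2.52, Hist1h2ab, H2afz and Cenpa), and 9 were higher and 5 lower with median-of-ratios scaling. The balance of the histone genes also depended on the controls, with 8 higher and 5 lower without controls 1 and 2 and 0 higher and 7 lower without controls 3 and 4. The camera adjusted p of these 6 lists was 0.525, 0.907, 0.744, 0.803, 0.964 and 0.544.

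Genes of stress responses, apoptosis and autophagy were lower more often than higher, and none of these lists passed the camera threshold. The lean to lower members stayed with median-of-ratios scaling and quantile normalization. All tested genes leaned the same way as deposited (1466 higher, 3981 lower) and with median-of-ratios scaling (2638 and 3188), but not with quantile normalization (2915 and 2847). Relative to all genes, the list medians as deposited were -0.19 for endoplasmic reticulum stress, -0.24 for heat shock and -0.36 for antioxidant genes. They were -0.32 for DNA damage, -0.3 for apoptosis and -0.51 for autophagy genes. In the per-library list means relative to all tested genes, a comparison added after seeing the data, the treated libraries lay below all controls for the lists of endoplasmic reticulum stress, heat shock, antioxidant, DNA damage and autophagy genes. The exact permutation p was 0.0286 for each (the smallest possible; adjusted p = 0.0629), and 0.857 for apoptosis genes. For genes of the response to foreign compounds the treated libraries lay above all controls, with means of -0.62 in controls and -0.26 with triclocarban (exact permutation p = 0.0286, adjusted p = 0.0629). The list means themselves overlapped, at 3.015, 3.045, 2.836 and 2.603 in controls 1 to 4 and 2.908, 2.982, 2.848 and 2.862 in treated libraries 1 to 4. This list therefore rose only relative to the mean of all tested genes, and its median relative to their median was 0. Of the endoplasmic reticulum and integrated stress response genes, 14 of 36 were lower, including Trib3 at -3.20, Ppp1r15b at -2.76 and Sesn2 at -2.53. The 1 higher member was Eif2ak4, a sensor of amino acid shortage, at 0.90. Heat shock genes were lower in 14 of 34, including Bag1 at -2.91, Hspa1a at -2.06 and Hspb1 at -3.20, and higher in 2, Dnajb4 and Hspe1. They were 6 higher and 13 lower with median-of-ratios scaling and 3 and 10 with quantile normalization. Antioxidant genes were lower in 16 of 38, including the peroxiredoxin gene Prdx4 at -2.67, the glutathione peroxidase gene Gpx4 at -2.51 and the metallothionein gene Mt1. Mt1 went from 677.4 ± 326 to 45.3 ± 14.3 FPKM (SD, n = 4 each). The 5 higher ones were Gsta4, Prdx1, Gstp1, Txn1 and the superoxide dismutase gene Sod1. The antioxidant list had 10 higher and 15 lower with median-of-ratios scaling, 9 and 14 with quantile normalization, and 11 and 18 without controls 1 and 2. Sod1 had 294.3 ± 41.0 and 574.5 ± 150.9 FPKM (log2 change 0.93, limma adjusted p = 0.0189). Its call was lost without control 3, triclocarban 1, 3 or 4 (adjusted p of 0.057, 0.0552, 0.0577 and 0.0661). DNA damage and p53 genes were lower in 19 of 45, including Sesn2, the kinase gene Atm at -2.19 and Plk3 at -2.45, and higher in 5, among them Ddb2, Xrcc5, Polk and Chek1. Trp53 itself had 18.1 ± 9.40 and 23.7 ± 4.78 FPKM (adjusted p = 0.305). Apoptosis genes were lower in 14 of 30, including Mcl1 at -2.54, and higher in 5 (Casp8 at 2.60, Bcl2l10, Birc3, Apaf1 and Birc5). Autophagy and lysosome genes were lower in 19 of 41, including Map1lc3a at -2.65, the cathepsin gene Ctsb at -3.10 and Atg4d, which was listed at 0 in 3 of the treated libraries, and higher in 4 (Pik3c3, Atg10, Atg5 and Optn). Genes of the response to foreign compounds were mostly below the filter: 13 of 36 were tested, of which Cyp2c29, Ahr and Esr2 were higher and Por lower. The balance was even, with 2 each way, without triclocarban library 2, and with 1 each way without controls 3 and 4. Ahr, the dioxin receptor, had 1.80 ± 0.75 and 4.52 ± 1.99 FPKM (log2 change 0.95, adjusted p = 0.028). That call was lost without control 3, control 4, triclocarban 2 or triclocarban 4 (adjusted p of 0.0655, 0.0871, 0.057 and 0.0669) and with no filter on low genes (adjusted p = 0.0729). Cyp1a1, a target of this receptor, was below the filter. The camera adjusted p of these 7 lists was 0.173, 0.582, 0.582, 0.525, 0.793, 0.239 and 0.641.

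In energy metabolism, 7 of 15 mitochondrially encoded genes were lower and 0 higher, including mt-Cytb, mt-Nd4l and mt-Nd3 at -1.62, -1.33 and -1.35. With the same direction, 4 were lower with median-of-ratios scaling or without controls 3 and 4. Nuclear genes of oxidative phosphorylation were higher in 17 of 77, such as Ndufa8 at 2.69, and lower in 27, such as Uqcrfs1 at -2.45 and Ndufa2 at -2.44. This turned to 26 higher and 20 lower with median-of-ratios scaling and to 24 and 20 with quantile normalization. Glycolysis and pyruvate genes were lower in 12 of 29, including Ldha at -2.12, Pdhb at -1.95 and the transporter gene Slc16a1 at -1.60, and higher in 5 (Dld, Ldhb, Dlat, Pdp1 and Tpi1). They were 6 higher and 9 lower with median-of-ratios scaling and 7 and 9 with quantile normalization. Lipid and sterol genes were lower in 18 of 38, including the mevalonate kinase gene Mvk at -2.51, the desaturase gene Scd1 at -2.97 and the squalene epoxidase gene Sqle at -1.81, and higher in 3 (Hadha, Idi1 and Nsdhl). They were 4 higher and 13 lower with median-of-ratios scaling and 4 and 11 with quantile normalization. The camera adjusted p of these 4 lists was 0.216, 0.803, 0.823 and 0.338.

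Markers of other cells that embryo samples could hold were also measured. Of the cumulus and granulosa markers, 6 of 26 were tested. Amhr2, Gja1 and Tnfaip6 were lower, at -3.40, -2.80 and -1.63, and Cyp19a1 and Fshr were higher. Of the sperm markers, 6 of 20 were tested, and Prm2 was higher at 1.57 and Ldhc lower at -1.81. Of the blood and epithelial markers, 5 of 20 were tested. The epithelial adhesion gene Epcam and the globin genes Hba-a2 and Hba-a1, which are near-identical copies, were lower, at -3.97, -2.26 and -1.65. The camera adjusted p of the 3 lists was 0.803, 0.803 and 0.216. In the list means relative to all tested genes, compared after seeing the data, the treated libraries lay below all controls for 2 of these lists. The means were -1.16 in controls and -1.69 with triclocarban for cumulus and granulosa markers, and 0.73 and -0.61 for blood and epithelial markers. The exact permutation p was 0.0286 for each (adjusted p = 0.0629), and 0.343 for sperm markers, whose groups overlapped.

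**Figure D3:**
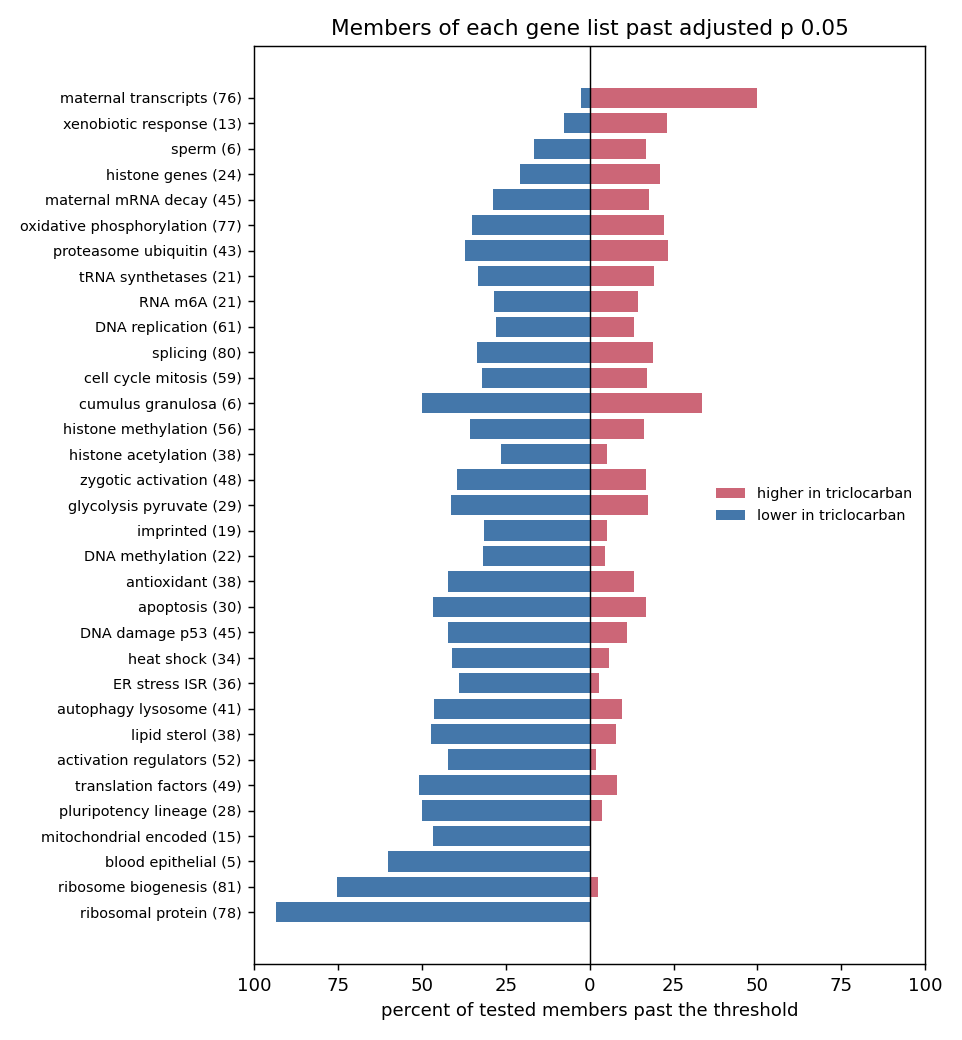
Percent of the tested members of each of 33 gene lists (number tested in parentheses) that were higher (right) or lower (left) with triclocarban past a limma adjusted p of 0.05, with FPKM as deposited. Oocyte-derived transcripts had 38 of 76 members higher and ribosomal protein genes 73 of 78 lower. The balance of maternal mRNA decay, oxidative phosphorylation, proteasome, cell cycle and tRNA synthetase genes turned to more higher than lower with median-of-ratios scaling, and that of the histone genes from even to more higher.

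Over the 33 lists, 3 were shifted by camera with the preset correlation (oocyte-derived transcripts up, ribosomal proteins and ribosome assembly down), 0 with an estimated correlation, and 26 by fry, which tests whether a list's genes move one way on balance and not against other genes. Camera's direction compares a list with the other genes, whose median was below 0. It was up for maternal mRNA decay, oxidative phosphorylation, proteasome, cell cycle, tRNA synthetase and sperm genes, whose median and mean were below 0. It was also up for the response to foreign compounds, where only the median was below 0, and for histone genes, where only the mean was. None of these lists passed the threshold with camera. Adjusted over the list alone, the counts of higher and lower members were 10 and 21 for histone methylation, 20 and 28 for oxidative phosphorylation, 7 and 16 for antioxidant and 5 and 21 for DNA damage genes. They were 2 and 1 for the response to foreign compounds, 5 and 26 for translation factors, 11 and 20 for cell cycle, 6 and 13 for glycolysis and 5 and 7 for tRNA synthetase genes. For the lists whose counts adjusted over the list alone are not given, they were the same as over all genes tested. In a comparison added after the data were seen, each list's mean relative to all tested genes separated the groups without overlap for 15 of 33 lists: 12 lower, and 3 higher (oocyte-derived transcripts, maternal mRNA decay and the response to foreign compounds). Each had an exact permutation p of 0.0286, the smallest possible, and a Benjamini-Hochberg adjusted p of 0.0629, which missed the threshold. For maternal mRNA decay and the response to foreign compounds, the list means themselves overlapped between the groups. These lists were higher only relative to the mean of all tested genes. Without controls 1 and 2, Pou5f1, Trp53, Tet3, Cnot6l and Dnmt1 passed the threshold as higher (limma adjusted p of 0.000565, 0.0144, 0.0248, 0.0398 and 0.0408). Without controls 3 and 4, the calls of Sod1 and Ahr were lost (adjusted p of 0.105 and 0.205). That of Zfp352 was lost without either pair (adjusted p of 0.0718 without controls 1 and 2 and 0.0563 without controls 3 and 4). Members that a count of 5 or fewer refers to, where the naming rule did not take them, were named after their values were seen.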

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

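The named genes, the oocyte-derived minus 2-cell-activated difference and 6 measures of the libraries, such as the FPKM sum, were checked within each group of 4 libraries, 256 checks in all. In 15 of them, each for a named gene, the highest or lowest library stood far from the other 3 (Dixon's ratio of gap to range past its 95% critical value), where chance flags about 1 in 20 groups, or 12.8 of 256. Triclocarban library 2, which had the lowest estimated depth at 6900000 fragments, was the distant one in 7 of the 15. It was high for Ing1 (ratio 0.853), Hspa1a (0.857) and Sqle (0.938) and low for Casp8 (0.833), Hspb1 (0.854), Phlda2 (0.865) and Sod1 (0.853), where its log2(FPKM + 1) was 8.47 against 9.29 to 9.44 in the other treated libraries. Triclocarban library 3 was high for Gabpa (0.894) and Atm (0.884). Triclocarban library 4 was low for Trib3 (0.838) and the only treated library above 0 for Atg4d (ratio 1). In the controls, library 1 was high for Snai1 (0.838) and Prm2 (0.867), library 3 high for Mcts2 (0.889) and library 4 high for Uqcrfs1 (0.853). No explanation of these single libraries was tested.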

How the results depend on the processing

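The leaving out of 2 controls together was chosen after the data were seen. In the settings not named here, the counts of higher and lower genes and of shifted lists stayed within 1.5 times the reported ones and the index difference kept its sign and its exact p of 0.0286. Higher genes numbered 2638 with median-of-ratios scaling, 2915 with quantile normalization, 953 to 1860 without one library at a time (971 without control 3, 953 without control 4), 2838 without controls 1 and 2 and 695 without controls 3 and 4; lower genes numbered 2492 with a filter of 5 FPKM, where 8050 genes were tested. Shifted lists numbered 8 with no filter, 5 with quantile normalization, 5 with the GC and length trend removed, 0 with an estimated correlation, 26 with fry and 5 without controls 1 and 2. The difference between the indices was 2.56 without controls 1 and 2 and 1.3 without controls 3 and 4 (exact p = 0.0667 each, the smallest possible with fewer libraries). The replicate number as a replicate block gave 1544 higher and 4061 lower genes and an index difference of 1.93 with an exact p of 0.125, the smallest that 4 pairs allow; same-numbered libraries had residual correlations of 0.338, 0.053, 0.095 and 0.104, and 3 of the 4 controls correlated best with their own number, a hint from the data and not the design. Of the named genes, Dnmt3b turned to 0.09 with quantile normalization and 0.01 without controls 1 and 2, and Cnot6l to -0.26 and Trp53 to -0.09 without controls 3 and 4; none of these passed the threshold as reported or turned. Of the other values of named genes under the alternatives, 2846 kept their direction and side of the threshold, 19 lost it and 15 gained it. Except where fewer genes or libraries entered, the cause was not tested. Lists were not run anew for the robust fit. What depth limits was not tested separately. In the simulation, which changed only 100 genes at each size, limma recovered 11% of changes of 1 log2 unit. With 42.1% of genes called in the real data, that share does not give the recovery in this comparison.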

Other observations

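The tests of depth, of the control axis with the residual variance of the main fit or from other genes, of cumulus cells and of lipid and sterol genes were chosen after the results they measure had been seen.

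Small nucleolar RNA genes, many of which lie in introns of ribosomal protein and translation genes, were lower in 26 of 68 tested and higher in 1, with a median log2 change of -0.80. For 44 of them with 1 protein-coding host gene on the same strand, the changes of snoRNA and host had a Spearman correlation of 0.51 across genes (permutation p = 0.00048), and 22 of the 34 hosts were lower and 0 higher. The permutation treated the 44 pairs as independent although some of the 34 hosts recur, so its p-value can be too small. Genes are not independent replicates, and a library of polyadenylated RNA measures snoRNA genes poorly, so reads from the host's introns may be part of this signal. An example chosen after its values were seen was Taf1d, at -2.07, which hosts several of these snoRNA genes. Processed pseudogenes named after ribosomal protein genes had a median of -1.35 (59 of 86 lower), against -0.46 for other processed pseudogenes, a difference of -0.89; the other set still holds unnamed ribosomal protein pseudogenes, so reads shared with the parent genes cannot be told apart from separate transcription.

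Short genes were lower more often than long ones. Of the 2680 protein-coding genes with the shortest genomic span 1108 were lower, and of the 2680 with the longest span 426. The hypothesis tested was the opposite one, that long genes, which take longer to transcribe, are lower. The Spearman correlation across genes between span and log2 change was 0.18, whose sign is against it, although the value lies outside the range set beforehand for excluding it.

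The broad change of the transcriptome might come from depth or scaling: lower depth with triclocarban would confine falls to rarely sampled genes, but with the genes in 4 equal groups by abundance 23.2% of the most abundant group were lower against 33.5% of the least abundant, a ratio of 0.69. The filter on FPKM had already taken out the rarest genes, so this ratio does not cover them. With the mitochondrial and 20 most abundant genes left out 5462 genes passed, 5311 of them among the 5447 called. With the GC and length trend removed 5315 passed, 4676 of them among the 5447. This argues against abundant genes or that trend as the whole cause. A count of genes cannot exclude scaling: quantile normalization passed 5762, of which 4265 were shared, and 50.6% instead of 26.9% were higher. A hypothesis of developmental timing is that treated embryos lie further back on the axis along which the controls differ: across genes, the treatment change correlated with the first component of the 4 controls alone with r = 0.64 (rho 0.66), and 80.9% of changed genes had its sign, where 54.1% would if independent (at least 90% was set beforehand for the axis as the whole cause and under 75% against it, so this share alone decides nothing). With a linear position on that axis as a covariate 3090 genes passed, 437 of them not among the 5447. With the axis taken from genes other than those tested, 3105 passed. With the residual variance of the main fit, a stricter test, 1503 passed (130 higher, 1373 lower), 27.6% as many as without the covariate. Treated libraries 1 to 4 lay at 89.3, 69.9, 73.3 and 72.9 on the axis, all beyond controls 1 to 4, at 56.6, 42.2, -50.4 and -48.4. The fit therefore extended a straight line past the controls. It cannot decide whether position on a course that is not straight is the whole cause. What the axis of the controls stands for was not tested, and a batch or the library preparation could also part the controls. Timing outside the range of the controls, such technical differences and a direct effect of triclocarban all stay open. Neither collection time nor batch is in the labels.

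Other splits of the 8 libraries were tested for both counts. Only 1 of 35 splits, the real one with 5447 genes, gave as many changed genes, and the highest other gave 2. No smaller share than 1 of 35 was possible. The first principal component, with 69.1% of the variance, parted the groups, so other splits left much of it in the residual error. The split count therefore shows that the libraries part by group and not what parted them. Chance could not be excluded for the number of shifted lists: 26 of the 35 splits shifted as many as the real 3, and the highest other shifted 10. The splits that part controls 1 and 2 from 3 and 4, with 2 treated libraries on each side, shifted 8 to 10. A split that put controls 1 to 3 with triclocarban library 2 also shifted 8. The cause of these shifts was not tested.

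Lower Amhr2 and Gja1 raised the question of cumulus or granulosa cells in the control samples. Such cells would bring their abundant transcripts, but only 3 of 26 markers (Amhr2, Gja1 and Tnfaip6) had at least 1 FPKM in controls and were lower, while Inha was listed at 0 in controls and Inhba, Vim, Has2 and Ptx3 were at 0.0113, 0.365, 0.23 and 0.0649 FPKM. Cyp19a1 went the other way, from 2.34 to 8.33 FPKM, while the low means of Star and Ptgs2 went from 0.506 to 0.251 and from 0.831 to 0.376. Only 5 of the 26 markers reached a mean of 1 FPKM in controls, so the count of lower markers could not be high. It is the near absence of abundant markers from the controls that argues against these cells as the source. Expression in the embryo itself was not tested.

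Among changed genes, 19.1% went against the control axis, and lipid and sterol genes did so more often, in 10 of 21 (Fisher's exact test adjusted over 30 lists, p = 0.0286). Ribosomal protein genes did so less often, in 1 of 73 (adjusted p = 0.000195), as did ribosome assembly genes, in 1 of 63 (adjusted p = 0.00052). The test treats genes as independent, which they are not, so these p-values can be too small. The lipid and sterol genes include Mvk, Cyp51, Fasn, Scd2 and Cpt1a, all lower with triclocarban, and were singled out after the values were seen, so the result is a hypothesis for a part of the response that differs from the axis of the controls.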
